A study of Mus musculus with 8 samples.

How the data were processed

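The arrays measured RNA of whole CD-1 mouse embryos, 4 hydroxyurea and 4 saline samples, on gestational day 9 and 3 h after injection of the dams. Groups were taken from the sample labels. The labels speak of 4 independent experiments but do not say which samples belong to the same experiment, nor whether each RNA came from its own litter or dam. The p-values therefore measure the spread between samples. Replicate numbers are only names and do not pair samples. The array identifiers place 2 hydroxyurea and 2 saline arrays on each of 2 slides. Slide 1 held hydroxyurea 1 and 2 with saline 1 and 2 and was scanned at 3 micrometres, and slide 2 held the others and was scanned at 5 micrometres.

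The deposited scanner files hold 1-colour Cy3 intensity values that the authors' processing notes and the file headers attribute to Agilent Feature Extraction 11.5.1.1, with background subtraction and no scaling between arrays in the processed signal. The authors' deposited table of differentially expressed genes holds log2 values, described in it only as normalized signal intensity. Comparison with the scanner files showed that its values are on the log2 scale and centred on each probe's median over the 8 arrays. Its normalization, test and threshold are not given in the sources used here. The table served only for a count of overlap.

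Each array held 59305 spots for 55681 probes, beside 3671 control spots. Between 151 and 315 spots per array that Feature Extraction marked as outliers were left out, and 0 spots were saturated. The mean of the log2 processed signal over a probe's spots gave its value, which was scaled by subtraction of the array's 75th percentile over probes that are not controls. Probes that Feature Extraction marked as well above background on at least 4 of the 8 arrays were kept, 30677 in number. The probe with the highest mean signal stood for its gene. This gave 23121 genes or unnamed features, of which 14631 were named genes. RefSeq accessions were matched to symbols in a RefSeq table of assembly GRCm38.p6, which was used only for names and gene lengths. Of the probes, 26582 took a symbol, 0 matched several and 29099 stayed unnamed, for 20145 symbols. Among all probes 28116 carried a RefSeq accession, 4226 an Ensembl transcript and 16194 a chromosome interval. Positions are those of the array files, whose headers on 4 arrays name mm9 (NCBI37), and none was converted.

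Differences between hydroxyurea and saline were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, no covariate), with p-values two-sided and adjusted by Benjamini and Hochberg over all features. Features with an adjusted p under 0.05 were called. An SE is that of the moderated fit. Lists of genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 27 lists, beside the number of members called over all genes and adjusted over the list alone. Camera tests whether the members of a list shift relative to all other genes. The 27 lists held 824 genes, 793 on the array by symbol and 736 measured, 8 of them in more than 1 list. The lists, the tests, the main settings, all but 2 of the alternatives and the rule for naming genes were written before the data were examined. The tests of receptor genes, of the histones and of the array hydroxyurea 2 and 3 further groups of genes were chosen after the data were seen. The median log2 difference over all features was 0.04 and moved to 0.158 with median centring, so all changes are relative to the scaling.

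Genes were named by rule: the 12 largest rises and 12 largest falls among called genes with a gene name whose groups did not overlap; per list the 3 called members with the lowest p, or the 2 lowest when none was called; and always Trp53, Cdkn1a, Mdm2, Ccng1, Bax, Fas, Rrm1, Rrm2, Rrm2b, Fos and Hmox1. This named 93 genes, 72 of them called, and some of these are not reported here. Of these, 21 had more than 1 probe past the filter, and among their 23 other probes 11 gave the same sign and the same side of the threshold, 7 the same sign and the other side, and 5 the opposite sign. Among other probes of all called named genes, 80.6% of 139 for higher genes and 84.1% of 69 for lower genes had the same sign, and 25.2% and 37.7% were called in the same direction.

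The steps were tested on simulated data with 200 changed genes. Of 100 genes changed by 1 on the log2 scale 37 were called, of 100 changed by 2 82 were called, and of 22921 unchanged genes 8 were called. Of 26 unchanged lists 0 were called, but the simulated genes were independent of each other, so this says nothing of lists whose genes vary together. With 4 arrays per group, smaller changes were thus often missed in the simulation, and the number of arrays limits precision. Fewer genes were called there than in the data, which makes the adjusted threshold stricter. The shares recovered therefore do not give the power of the real comparison.

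Alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, other filters on dim probes, the mean of a gene's probes or all probes, the slide or the position within the slide as a block, each slide alone, another model of spread, array weights, other thresholds, other tests of lists and each array left out in turn. The files hold no mean pixel signal, so normexp used the median pixel signal with the median local background. Measures of array quality were compared by two-sided exact permutation over 70 relabelings, whose smallest p is 0.0286. The 35 splits of the 8 arrays into 4 and 4 were run through the same fit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The spike-in controls were not used for scaling, and the genes under the chromosome intervals were not analysed here.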

Results

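Whole embryos of CD-1 mice, an outbred stock, were compared 3 h after their dams received an intraperitoneal injection of hydroxyurea at 400 mg/kg or of saline on gestational day 9, when the organs begin to form. Hydroxyurea inhibits ribonucleotide reductase, the enzyme that makes the deoxyribonucleotides for DNA synthesis. The series' title names p53 signalling as its subject. Total RNA of 4 hydroxyurea samples and 4 saline samples was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays with 55681 probes. The arrays lay on 2 slides, each with 2 arrays of each group. Between 48.7% (hydroxyurea 3) and 62.3% (saline 1) of the spots were well above background. The 75th percentile of the signal, to which each array was scaled, lay between 249 (hydroxyurea 3) and 516 (saline 2). The number of arrays limits the precision of every difference below.

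The main comparison asked which transcripts differed between hydroxyurea and saline embryos. Of 50 measured p53 targets 31 were higher in hydroxyurea embryos (adjusted p = 0.088 for the list with an estimated correlation). By the probe that stood for each gene and the main scaling, Ccng1, Cdkn1a, Fas, Pmaip1, Trp53inp1 and Zfp365 were all at least 8.11-fold above saline. Of 43 replication-dependent histone genes 22 were lower, with H2bc18 and H2ac4 falling furthest, and of 43 mitosis genes 15 were lower (adjusted p = 0.223 for each list with an estimated correlation). Members also passed in the lists of replication (4 of 44 higher), the immediate early response (10 of 34 higher, 2 lower) and inflammation (4 of 19 higher). So did members of the lists of neural progenitors (3 of 34 lower) and of limb bud and Hox genes (3 of 37 lower). These lists passed the set test, but with an estimated correlation each adjusted p was at least 0.179. Of 23121 genes and unnamed features tested, 1429 passed an adjusted p of 0.05 with limma, 642 higher and 787 lower in hydroxyurea. Among the 14631 named genes, 532 were higher and 297 lower. The 4 hydroxyurea arrays and the 4 saline arrays did not overlap for 3580 features (15.5%, against 2.86% by chance) and for 1413 of the 1429 called. The larger share of falls depended on the processing. It held or grew with all probes tested as they are (777 higher, 1319 lower), with the position on the slide as a block (452 and 759), with no filter on dim probes (269 and 346) and with median centring (472 and 596). It turned with other choices: 1151 were higher and 949 lower with normexp, 944 and 899 with quantile normalization, 807 and 746 among probes well above background on all 8 arrays, and 1973 and 1766 without the array hydroxyurea 2. With the slide as a block, 1069 features were called, 450 higher and 619 lower. Slide 1 alone gave 59 calls and slide 2 alone gave 3. No feature passed a test of whether the difference itself differed between the slides with limma (0 at an adjusted p of 0.05, 218 at an unadjusted p of 0.05). The 218 are fewer than chance alone would give, so this test was weak and does not show that the slides agree. The count rose to 3739 without the array hydroxyurea 2, and fell to 609 without hydroxyurea 1, 524 without hydroxyurea 4, 793 without saline 1, 671 without saline 2, 639 without saline 3 and 772 without saline 4.

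The list of p53 targets passed as higher: of 50 measured members 31 were higher, 0 were lower and 19 did not pass, and adjusted over the list alone 37 were higher. Their median log2 difference was 0.98 and their mean 1.40 (adjusted p = 7.2e-27 over 27 lists, and adjusted p = 0.088 with an estimated correlation). Ccng1 (NM_009831), which encodes cyclin G1, rose 9.21-fold, a log2 difference of 3.20 ± 0.14 (SE, n = 4 per group, adjusted p = 1.9e-05). Cdkn1a (NM_007669), the gene of the cyclin-dependent kinase inhibitor p21, rose 8.11-fold (3.02 ± 0.24 on the log2 scale, adjusted p = 0.00027), and its other probe gave 3.67. Trp53inp1, a stress-induced gene that promotes cell death and autophagy, rose by 3.23 (SE 0.17), and its other probe gave 2.18 and passed. Zfp365, a zinc finger gene linked to genome stability, rose by 3.60 (SE 0.19). Pmaip1, which encodes the BH3-only protein Noxa, rose by 3.61 (SE 0.22) and the death receptor gene Fas by 3.46 (SE 0.23). Eda2r, a receptor of the tumour necrosis factor receptor family, was at least 3.56-fold higher (adjusted p = 0.002). Tap1, which carries peptides into the endoplasmic reticulum for presentation, was at least 6.93-fold higher (adjusted p = 0.00015). With normexp, which compresses dim signals, the log2 difference was 0.78 for Eda2r and 1.16 for Tap1. Such a bound is given where no array of a group was well above background for the probe. It sets the mean of the brighter group against the lowest signal that counted as well above background on the dimmer arrays, or their own signal where higher. The bound holds for the main scaling only and includes no sampling error. Within the slides the median of the p53 targets was 0.92 and 1.09, and with the slide as a block the list had an adjusted p of 1.3e-25.

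**Figure D1:**
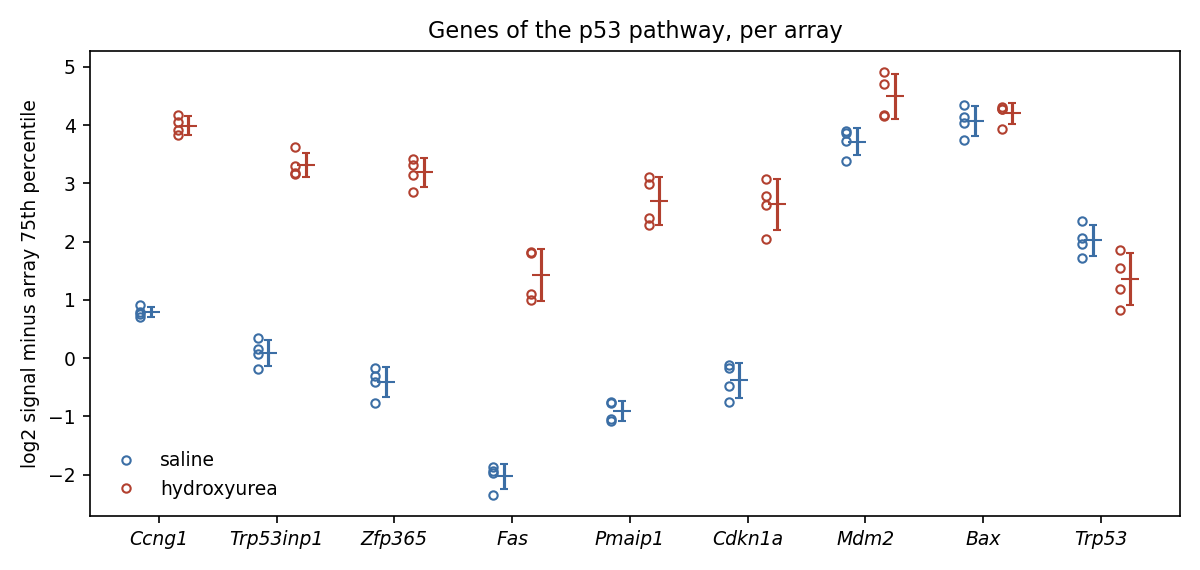
Log2 signal minus the array's 75th percentile (vertical axis) for 9 genes of the p53 pathway (horizontal axis), with a circle per array in saline (blue) and hydroxyurea (red) and a bar for the mean ± SD of 4 arrays. For Ccng1 the hydroxyurea arrays lay between 3.83 and 4.18 and the saline arrays between 0.70 and 0.92, while for Bax and Trp53 the groups overlapped.

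Several central genes of the pathway did not pass the test. Trp53 (NM_011640), the gene of p53 itself, had a log2 difference of -0.67 ± 0.24 (SE, n = 4 per group, adjusted p = 0.13). Mdm2, whose product marks p53 for degradation, stood at 0.78 ± 0.21 (adjusted p = 0.066), and passed without the array hydroxyurea 2 (adjusted p = 0.033) and with normexp (0.013). Bax, which encodes a pore-forming protein of the mitochondrial death pathway, stood at 0.13 ± 0.17 (adjusted p = 0.68). Of the 19 measured genes of p53 and its regulators 3 rose, 0 fell and 16 did not pass, and adjusted over the list alone 5 were higher and 1 lower. The 3 were Ppp1r13l (1.01), which encodes an inhibitor of p53, Atm (0.66), the kinase gene of the response to DNA breaks, and Rchy1 (0.56), a ubiquitin ligase gene that acts on p53. Another Atm probe gave 0.53 and did not pass. The list as a whole was not called (adjusted p = 0.387), its median of -0.0041 lay below 0 and its mean of 0.065 above, and the median changed sign with other scalings. The calls of Ppp1r13l were lost without hydroxyurea 1 or hydroxyurea 4, those of Atm without any single array but hydroxyurea 2 or saline 1, and those of Rchy1 without any but hydroxyurea 2. Rchy1 did not pass with normexp (0.36 on the log2 scale), with the slide as a block (adjusted p = 0.067) or with median centring (0.098), and Atm did not pass with median centring (0.063) or the mean of its probes (0.108).

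The list of the BCL2 family and the caspases passed as higher, with 3 of 29 measured members higher, 0 lower and 26 not past (adjusted over the list alone, 4 higher). Their median was 0.26 (adjusted p = 0.0019, and adjusted p = 0.575 with an estimated correlation). Those higher included Bik (0.95), a BH3-only gene, and Dffb (0.94), which encodes the nuclease that breaks DNA between nucleosomes in dying cells. The call of Dffb was lost without hydroxyurea 1 or hydroxyurea 4, and Bik stood at 0.60 with normexp and still passed. The slide medians of the list were 0.30 and 0.22, and with the slide as a block its adjusted p was 0.0023.

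The list of replication-dependent histone genes, which lack a poly(A) tail in their mature transcripts and are made during S phase, passed the set test as lower (adjusted p = 5.1e-19, and adjusted p = 0.223 with an estimated correlation). Of 43 measured members 22 were lower, 0 were higher and 21 did not pass, and adjusted over the list alone 30 were lower. H2bc18 fell by 4.52 (SE 0.38, n = 4 per group, adjusted p = 0.0003), H2ac4 fell by 3.67 (SE 0.39, adjusted p = 0.0014) and H3c14 fell by 2.67 (SE 0.26, adjusted p = 0.00091), all on the log2 scale. Calls came from each family, with 4 of 4 measured members of H1, 5 of 13 of H2A, 3 of 9 of H2B, 3 of 8 of H3 and 7 of 9 of H4. The genes within a family are near copies of each other in their coding parts, so the probes may not separate them. The median of the list was -1.14, with -0.90 on slide 1 and -1.36 on slide 2, and an adjusted p of 2.6e-18 with the slide as a block. On the array saline 1 the mean of the list lay 0.35 below the saline mean (-0.35), away from the other saline arrays at 0.11 to 0.12.

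**Figure D2:**
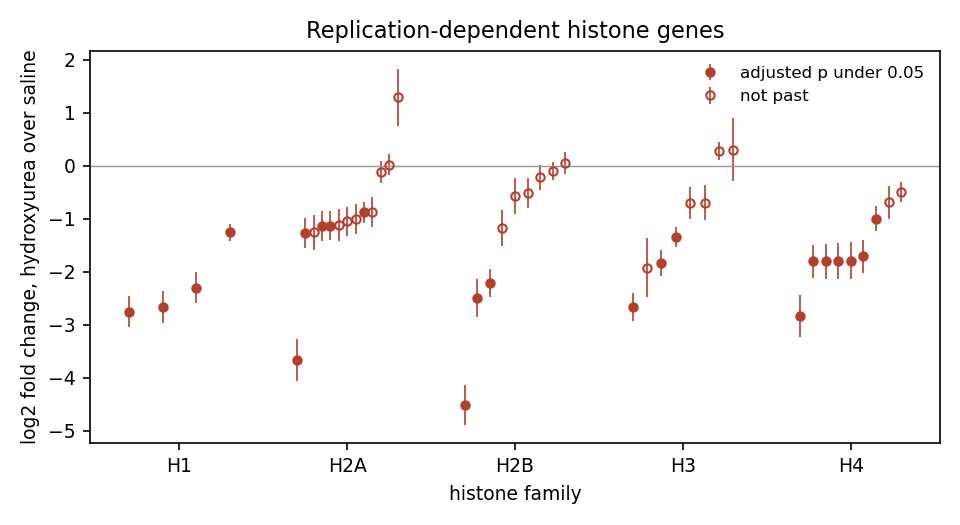
Log2 fold change of hydroxyurea over saline (vertical axis) for 43 replication-dependent histone genes by family (horizontal axis), with a point per gene, bars of 1 SE, and filled points for an adjusted p under 0.05. The 22 filled points all lie below 0, down to -4.52 for H2bc18.

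The mitosis list also passed as lower (adjusted p = 2.3e-14, and adjusted p = 0.223 with an estimated correlation), with 15 of 43 measured members lower, 0 higher and 28 not past (adjusted over the list alone, 27 lower). Hmmr, which encodes a spindle protein, fell by 1.22 (SE 0.13, n = 4 per group, adjusted p = 0.0011). Ube2c, the gene of a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell by 1.32 (SE 0.15), and Tpx2, the gene of a spindle assembly factor that activates Aurora A, fell by 1.17 (SE 0.15). Another Tpx2 probe gave -2.38, and the mean of both probes -1.77. The mitosis list had a median of -0.61, with -0.58 on slide 1, -0.51 on slide 2 and an adjusted p of 1.3e-13 with the slide as a block. The list of replication and E2F passed as higher (adjusted p = 8.6e-06, and adjusted p = 0.551 with an estimated correlation), with 4 of 44 measured members higher, 0 lower and 40 not past (adjusted over the list alone, 10 higher). Ccne1, the cyclin E1 gene of entry into S phase, rose by 0.91 (SE 0.17, adjusted p = 0.015), and its other probe gave 0.88 and did not pass. Slbp, whose product binds the stem-loop of histone mRNA, rose by 1.08 (SE 0.22), and Orc6, of the origin recognition complex, rose by 0.81 (SE 0.19). For the whole list the median was 0.35, with 0.35 on slide 1, 0.33 on slide 2 and an adjusted p of 1.1e-05 with the slide as a block. The call of Slbp was lost without hydroxyurea 1, hydroxyurea 4 or saline 2, and that of Orc6 without any single array but hydroxyurea 2, with the slide as a block (adjusted p = 0.066) and with median centring (0.065).

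Transcripts of the enzyme that hydroxyurea inhibits did not pass the test. The ribonucleotide reductase subunit genes Rrm1 and Rrm2 stood at 0.21 ± 0.13 (SE, n = 4 per group, adjusted p = 0.37) and 0.39 ± 0.17 (adjusted p = 0.19), of which Rrm2 passed with normexp (adjusted p = 0.042) and quantile normalization (0.041). Rrm2b, the p53-inducible subunit gene, stood at 0.97 ± 0.29 (adjusted p = 0.080), was well above background on 2 of the 4 saline arrays, and passed without hydroxyurea 2 (adjusted p = 0.014). The list of ribonucleotide reduction and dNTP supply passed as higher (adjusted p = 0.0099, and adjusted p = 0.657 with an estimated correlation), with 2 of 18 measured members higher, 0 lower and 16 not past (adjusted over the list alone, 4 higher). The 2 were the kinase genes Tk1 (0.69), of thymidine, and Dtymk (0.59), of thymidylate, which each lost their call without any single array but hydroxyurea 2; another Dtymk probe gave 0.60 and did not pass. Dtymk did not pass with the slide as a block (adjusted p = 0.057), median centring (0.09) or the mean of its probes (0.067), and Tk1 did not with median centring (0.054). That list's median was 0.20, on each slide 0.20 and 0.19, with an adjusted p of 0.01 with the slide as a block and 0.0556 without the array saline 4.

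The list of replication stress and DNA repair passed as higher (adjusted p = 0.0019, and adjusted p = 0.408 with an estimated correlation), with 4 of 57 measured members higher, 0 lower and 53 not past (adjusted over the list alone, 5 higher and 1 lower). Rev1, a scaffold gene of translesion synthesis, rose by 0.96 (SE 0.17, n = 4 per group, adjusted p = 0.014), and Fancb, of the Fanconi anaemia core complex, rose by 0.72 (SE 0.14). Bard1, the partner of BRCA1, passed at 0.77, but its other probes gave -0.16 and -0.91, and the mean of its probes gave -0.0961. The median of the list was 0.27, with 0.26 on slide 1, 0.24 on slide 2 and an adjusted p of 0.0024 with the slide as a block. The call of Rev1 was lost without hydroxyurea 4, that of Fancb without hydroxyurea 1, hydroxyurea 4, saline 1 or saline 3, and that of Bard1 without any single array but hydroxyurea 2 or hydroxyurea 3.

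The list of immediate early and AP-1 genes, which respond to stimuli within minutes, passed as higher (adjusted p = 0.0019, and adjusted p = 0.341 with an estimated correlation), with 10 of 34 measured members higher, 2 lower and 22 not past (adjusted over the list alone, 11 higher and 2 lower). Egr1, a zinc finger factor gene, rose by 2.07 (SE 0.18, n = 4 per group, adjusted p = 0.00044). Fos, which encodes a subunit of AP-1, rose by 2.06 (SE 0.21, adjusted p = 0.0011), was well above background on 2 of the 4 saline arrays, and stood at 0.67 with normexp. Spry2, which encodes an inhibitor of receptor tyrosine kinase signalling, was at least 3.91-fold lower in hydroxyurea (adjusted p = 0.0041, -0.70 with normexp). The median of the list was 0.17, with 0.14 on slide 1, 0.37 on slide 2 and an adjusted p of 0.0023 with the slide as a block. The list of inflammation and interferon passed as higher (adjusted p = 0.0007, and adjusted p = 0.179 with an estimated correlation), with 4 of 19 measured members higher, 0 lower and 15 not past (adjusted over the list alone, 11 higher). They included Ccl2 (1.62), a monocyte chemoattractant gene, Irf1 (1.21), an interferon regulatory factor gene, and Relb (1.01), an NF-kappaB subunit gene whose other probe gave 0.92 and passed. Ccl2 stood at 0.75 with normexp and passed. The median of that list was 0.60, with 0.54 on slide 1, 0.60 on slide 2, 0.27 with normexp and an adjusted p of 0.00053 with the slide as a block.

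Among the other stress lists, only that of hypoxia and glycolysis passed (adjusted p = 0.046, and adjusted p = 0.785 with an estimated correlation), with 2 of 29 measured members higher, 0 lower and 27 not past (adjusted over the list alone, 3 higher). The 2 were Bhlhe40 (0.996), a hypoxia-inducible repressor gene that stood at 0.53 with normexp, and the hexokinase gene Hk1 (1.03), whose other probe gave 0.18. The mean of the Hk1 probes, 0.61, did not pass. The median of the list was 0.23, with 0.11 on slide 1, 0.25 on slide 2 and an adjusted p of 0.047 with the slide as a block. It did not pass on slide 1 alone (adjusted p = 0.312), after normexp (0.0709) or quantile normalization (0.0503), with no filter on dim probes (0.109), or without hydroxyurea 1 (0.079), hydroxyurea 3 (0.109) or saline 4 (0.349). The list of NRF2 and oxidative stress was not called (adjusted p = 0.387, median 0.084), with 1 of 32 measured members higher, 1 lower and 30 not past, and the same counts adjusted over the list alone. Nfe2l2, the gene of NRF2 itself, rose by 0.86 (SE 0.14, n = 4 per group, adjusted p = 0.0086), Gclm, a subunit gene of glutathione synthesis, fell by 0.69 (SE 0.17, adjusted p = 0.045, but 0.064 with the slide as a block and 0.184 with median centring, and lost without any single array but hydroxyurea 2), and Hmox1, the haem oxygenase 1 gene, stood at 0.44 ± 0.16 (adjusted p = 0.14). The list of ATF4 and the unfolded protein response was not called either (adjusted p = 0.387, median 0.046, of the opposite sign after normexp), with 4 of 33 measured members higher, 0 lower and 29 not past (adjusted over the list alone, 4 higher and 1 lower). Chac1 (1.73), which degrades glutathione, and Trib3 (1.34), a pseudokinase gene induced by ATF4, rose, as did Edem1 (0.67), of the degradation of misfolded proteins, whose call was lost with the slide as a block (adjusted p = 0.0502), with median centring (0.06) and without any single array but hydroxyurea 2 or hydroxyurea 3. In the heat shock list 0 of 19 measured members passed, over all genes or adjusted over the list alone (median 0.13, adjusted p = 0.387), with Hspb8 at 0.38 and Hsf2 at 0.49, of which Hsf2 passed without hydroxyurea 2 (adjusted p = 0.028). In the iron handling list 0 of 15 passed in either way (median 0.011, adjusted p = 0.824), with Fth1 at 0.46 and Fech at 0.42, which both passed without hydroxyurea 2 (adjusted p = 0.036 and 0.048), as Fth1 did with normexp (0.022) and quantile normalization (0.037).

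Lists of embryonic patterning genes passed as lower or were not called. The list of neural progenitor and early neuron genes passed as lower, with 3 of 34 measured members lower, 0 higher and 31 not past (adjusted over the list alone, 7 lower). The median was -0.29 (adjusted p = 0.0019, and adjusted p = 0.408 with an estimated correlation), with -0.29 on each slide and an adjusted p of 0.0023 with the slide as a block. Six3, a homeobox gene of the forebrain and eye, fell by 1.46 (SE 0.21, n = 4 per group, adjusted p = 0.0057). Lmx1b (-0.77), a homeobox gene of the midbrain and dorsal limb, and Nkx2-2 (-0.77), of the ventral neural tube, also fell, although another Nkx2-2 probe gave -0.014 and the mean of both, -0.39, did not pass. The call of Lmx1b was lost without any single array but hydroxyurea 2 or saline 4, and that of Nkx2-2 without any but hydroxyurea 2 or hydroxyurea 3. Another Lmx1b probe, at -0.67, did not pass, and with normexp Lmx1b stood at -0.38. Lmx1b did not pass with median centring (adjusted p = 0.104), and Nkx2-2 did not with median centring (0.118), normexp (0.061) or the slide as a block (0.066). The list of limb bud and Hox genes passed as lower (adjusted p = 0.0029, and adjusted p = 0.408 with an estimated correlation), with 3 of 37 measured members lower, 0 higher and 34 not past (adjusted over the list alone, 4 lower). The median was -0.24, with -0.25 on slide 1, -0.22 on slide 2 and an adjusted p of 0.0034 with the slide as a block. The 3 were Tbx5 (-0.77), a T-box gene of forelimb and heart, Hoxa13 (-1.45), of the distal limb, and Hoxd9 (-0.56), of the HoxD cluster. The call of Tbx5 was lost without any single array but hydroxyurea 2 or hydroxyurea 3, that of Hoxa13 without any but saline 3, and that of Hoxd9 without any but hydroxyurea 2. With the slide as a block none of the 3 passed (adjusted p = 0.057 for Tbx5, 0.057 for Hoxa13 and 0.068 for Hoxd9), nor did Tbx5 (0.102) and Hoxd9 (0.217) with median centring or Hoxa13 (0.068) with quantile normalization. Hoxa13 was well above background on 3 of the 4 hydroxyurea arrays and stood at -0.31 with normexp, not past the threshold.

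In the segmentation clock and presomitic mesoderm list, 1 of 31 measured members fell, 0 rose and 30 did not pass, also when adjusted over the list alone. The 1 was Lfng, the Notch-modifying gene that oscillates in the presomitic mesoderm, which fell by 1.48 (SE 0.15, n = 4 per group, adjusted p = 0.0011). The list was not called (adjusted p = 0.209), its median of -0.034 turned positive with median centring, and it passed without hydroxyurea 1 (adjusted p = 0.046). Of the 20 measured neural crest genes 3 fell, 0 rose and 17 did not pass, with the same counts adjusted over the list alone. These included Sox10 (-0.78), which marks migrating crest cells, and Dlx5 (-1.19), of the pharyngeal arches. The median of the list was 0.018 and its mean -0.11, the test pointed down without passing (adjusted p = 0.387), and the sign of the median changed with quantile normalization and normexp. Sox10 lost its call without hydroxyurea 4, saline 3 or saline 4, and Dlx5 without any single array but hydroxyurea 2 or hydroxyurea 3. With normexp Dlx5 stood at -0.71, with the slide as a block it did not pass (adjusted p = 0.074), and with median centring Sox10 did not (0.104).

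Markers of cell types and neighbouring tissues were examined for shifts in what the samples held. In the heart list 2 of 24 measured members rose, 1 fell and 21 did not pass (adjusted over the list alone, 4 higher and 1 lower), with a median of 0.20 that was not called (adjusted p = 0.071). Hand1, a factor gene of the heart and extraembryonic tissue, fell by 1.42 (SE 0.22, n = 4 per group, adjusted p = 0.0083), while the calcium channel gene Ryr2 (0.71) and the myosin gene Myh7 (0.63) rose. The call of Ryr2 (0.42 with normexp) was lost without any single array but hydroxyurea 2 or hydroxyurea 3, and that of Myh7 without any but hydroxyurea 2, and neither passed with the slide as a block (adjusted p = 0.0504 and 0.0506) nor Myh7 with median centring (0.069). The heart list passed without hydroxyurea 1 (adjusted p = 0.046), saline 2 (0.027) or saline 3 (0.04). In the endothelium list 1 of 20 measured members fell, 0 rose and 19 did not pass (adjusted over the list alone, 4 higher and 3 lower), with a median of 0.096 (adjusted p = 0.557). The 1 was the factor gene Erg (-0.94), whose call was lost with normexp (-0.39), with the slide as a block (adjusted p = 0.051), with median centring (0.086) and without any single array but hydroxyurea 2, hydroxyurea 3 or saline 1. No gene passed in the list of primitive red cells (0 of 19; median -0.019, mean 0.15, test downward, adjusted p = 0.892), with Ermap at -0.87, past the threshold without hydroxyurea 2 (adjusted p = 0.018). The sign of that median changed with other scalings. In the yolk sac endoderm list 0 of 23 passed, with a median of -0.76 (adjusted p = 0.054, and 0.045 with the slide as a block), -0.35 on slide 1 and -1.12 on slide 2. It passed with normexp (adjusted p = 0.029), with no filter on dim probes (0.009) and on slide 2 alone (3.8e-07), and not on slide 1 alone (0.348). Its mean on single arrays ran from -1.88 (hydroxyurea 3) to 1.97 (saline 2) relative to the saline mean, with Apoa4 at -1.71 ± 0.91 and Lrp2 at 0.43 ± 0.23 (SE). The yolk sac list had an adjusted p of 0.974 without saline 2, of 0.0023 without hydroxyurea 1, of 0.00044 without saline 1, of 0.022 without saline 3 and of 0.047 without saline 4. In the list of placenta and decidua 1 of 17 rose, 0 fell and 16 did not pass (adjusted over the list alone, 1 higher and 1 lower; median 0.21, adjusted p = 0.459). The 1 was Ascl2 (0.91), a trophoblast factor gene, whose call was lost without any single array but hydroxyurea 2 or hydroxyurea 3. Of 16 maternal blood and leukocyte genes 0 passed (median 0.062, mean -0.0012, test upward, adjusted p = 0.892), with Csf1r at -1.51 (past without hydroxyurea 2, adjusted p = 0.034) and Laptm5 at 0.78 (past with normexp, adjusted p = 0.049). Of the 4 measured genes among Xist and the Y-linked genes 0 passed (median 0.79, adjusted p = 0.070, and 0.062 with the slide as a block), with Xist at 1.54 and Eif2s3y at 0.70; the list passed without hydroxyurea 1 (adjusted p = 0.023) or saline 4 (0.046). The housekeeping list held 0 of 15 calls (median 0.13, adjusted p = 0.387), with Gusb at 0.50 and Hprt at 0.64, both past without hydroxyurea 2 (adjusted p = 0.028 and 0.011) and with normexp (0.038 and 0.017), and Hprt also with quantile normalization (0.028). Adjusted over the list alone, 0 members passed in the lists of red cells, yolk sac, maternal blood, Xist with the Y-linked genes, and housekeeping.

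**Figure D3:**
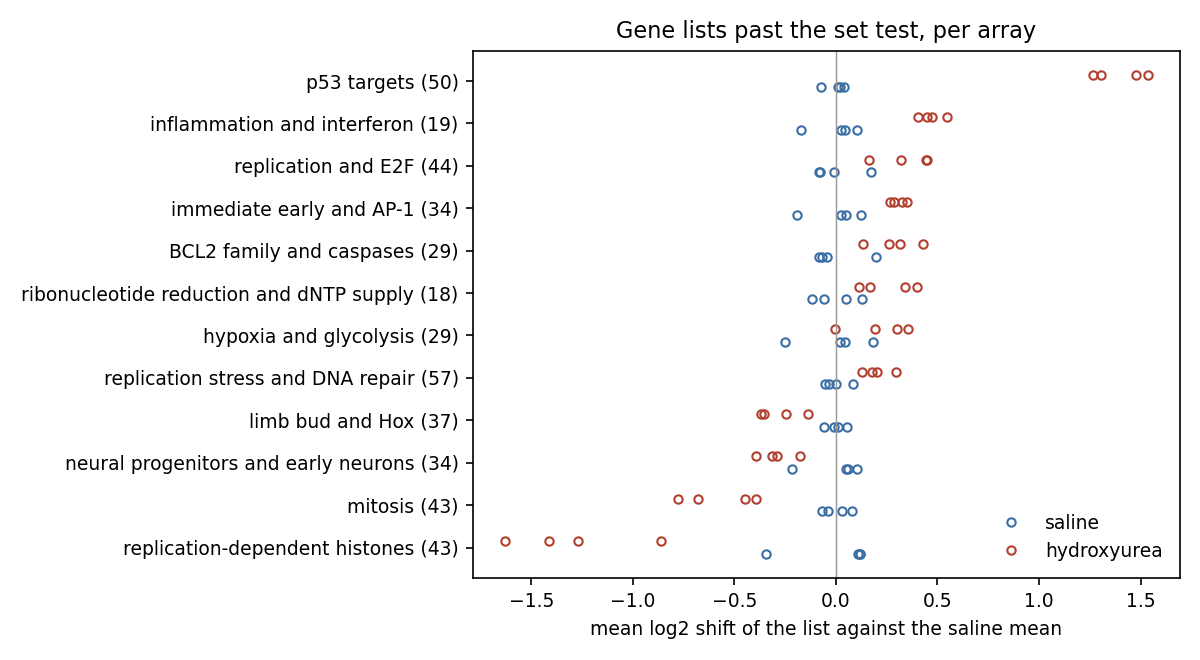
Mean log2 shift of each list's members against the saline mean (horizontal axis) for the 12 lists past the set test (vertical axis, measured members in parentheses), with a circle per array in saline (blue) and hydroxyurea (red). The p53 targets lay between 1.27 and 1.54 on the hydroxyurea arrays and the histones between -1.63 and -0.86.

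Of the 27 lists 12 passed, 8 higher and 4 lower, each with the same sign of its median under every scaling tried. With the correlation between genes estimated from these arrays, 0 lists passed with limma's camera at an adjusted p of 0.05 (4 at an unadjusted p of 0.05, smallest adjusted p = 0.088). The directional test of fry, also from limma, called 12 lists, of which 10 were the same in the same direction. In an exact permutation test of the array labels 0 lists passed after adjustment and 8 had p = 0.0286, the smallest that 4 against 4 arrays can give. Of the 35 ways to split the 8 arrays into 4 and 4, 6 gave at least 12 lists, the true one among them, while for single genes no other split gave more than 1 call. All 5 others put 3 hydroxyurea arrays with 1 saline array or the reverse, which keeps part of the treatment difference, and the 18 splits with 2 arrays of each group on both sides called at most 9. By the count over all splits, chance is not excluded for the number of lists.

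Several of the largest rises among named genes lay outside the list of p53 targets. Svop, which encodes a synaptic vesicle protein, rose by 4.01 (SE 0.30, n = 4 per group, adjusted p = 0.00017), and Ddit4l, an inhibitor gene of mTOR signalling, rose by 3.37 (SE 0.22, adjusted p = 8.7e-05). The leukotriene receptor gene Ltb4r1 (3.26, well above background on 3 of 4 saline arrays, 1.74 with normexp) and the SLIT receptor gene Eva1c (3.24) rose as well. The angiotensin receptor gene Agtr1b was at least 3.94-fold higher (adjusted p = 9.2e-05), the nucleotide receptor gene P2ry6 at least 4.46-fold (adjusted p = 0.00015) and the epidermal factor gene Zfp750 at least 5.69-fold (adjusted p = 0.00026). With normexp these stood at 0.94, 0.76 and 1.08. Among named genes the largest falls were those of Syt10, a synaptotagmin gene (-6.96, SE 0.48, n = 4 per group, adjusted p = 0.00013), and Prm1, the sperm protamine gene (-5.86, SE 0.43). Neither gene had another probe past the filter, so each fall rests on a single probe. In saline the scaled log2 signal of the Syt10 probe averaged 6.68, close to that of Rrm2 (6.57), and that of the Prm1 probe 1.18. Whether the signal of either probe came from the named mRNA was not tested, so these may not be falls of the 2 genes. Tox4, a chromatin-binding factor gene (-4.73), and Dnm1, the dynamin 1 gene (-3.34), fell by the probe that stood for them, while their other probes gave 0.43 and 0.16, and the means of their probes -2.15 and -1.59. Mfsd4a, a transporter family gene (-4.21, other probe -0.40), Amer3, which binds APC (-4.01), Amt, of glycine cleavage (-3.87), Lgr4, an R-spondin receptor gene (-3.59), and H1f0, a linker histone gene outside the replication-dependent set (-3.11), also fell. On the hydroxyurea arrays Mfsd4a was well above background on 3 of 4, H1f0 on 2 of 4, and Prm1, Amer3, Amt and Lgr4 on 1 of 4, so the sizes of these falls are uncertain. With normexp they were -1.36 for Mfsd4a, -1.69 for H1f0, -3.32 for Prm1, -1.27 for Amer3, -1.35 for Amt and -1.10 for Lgr4. Lgr4 and H1f0 lost their calls without any single array but hydroxyurea 2, and H1f0 with the slide as a block (adjusted p = 0.053).

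Features that the array names only by a stretch of a chromosome fell more often than named genes. Of 2757 such intervals 304 (11.03%) were lower and 31 (1.12%) higher, against 297 (2.03%) and 532 (3.64%) of 14631 named genes. Each named gene was counted once, while intervals that overlap each other were counted apart. The shares therefore compare unlike units. Ensembl transcripts without a gene symbol were lower in 67 (3.82%) and higher in 38 (2.17%) of 1754 cases, and features with other identifiers in 119 (2.99%) and 41 (1.03%) of 3979. The interval with the lowest p lay on chromosome 15 from 79764481 to 79809909 on the forward strand and fell by 2.78 (SE 0.16, n = 4 per group, adjusted p = 5.7e-05). The next lay on chromosome 2 from 130697320 to 130729670 on the reverse strand and fell by 3.00 (SE 0.19, adjusted p = 8.7e-05). Both positions are as the arrays give them, in the mouse build mm9 per the headers of 4 arrays, and which genes lie there was not analysed here. With named genes only, a choice made after seeing the data, 771 were called, 491 higher and 280 lower.

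**Figure D4:**
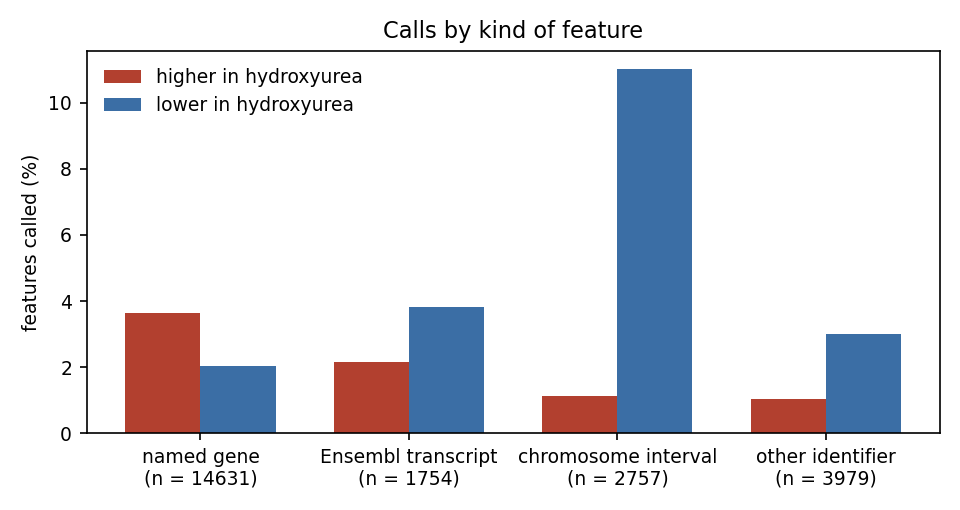
Percentage of tested features called higher (red) or lower (blue) in hydroxyurea (vertical axis) by kind of feature (horizontal axis, number tested in parentheses). Chromosome intervals were lower in 11.03% of cases and named genes in 2.03%.

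The authors' deposited table of differentially expressed genes held 553 probes that were higher and 793 that were lower in hydroxyurea by the means of its values. The smallest difference in the authors' deposited table was 1.502-fold. Its probes stood for 1138 genes or features, all tested here, of which 952 were called here in the same direction, 1102 had the same sign and 1 was called in the opposite direction. That 1, named here after its values were seen, was an interval on chromosome 5 whose brightest probe gave 1.08. A further 476 features were called here and absent there. The table was made from the same arrays, and its values nearly equalled those scaled here (r = 0.999977). The overlap therefore compares tests, thresholds and the choice of probe for a gene, and is no independent evidence.

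Measures of array quality did not separate the groups. The share of spots well above background was 54.4% ± 3.91 (SD, n = 4) in hydroxyurea and 57.7% ± 4.07 in saline (exact permutation p = 0.343, two-sided), with a difference of -4.31 percentage points on slide 1 and -2.22 on slide 2. The 75th percentile of the signal was 375 ± 99.4 and 397 ± 110.0 (exact permutation p = 0.8), with a difference of -106 on slide 1 and 61.4 on slide 2. Exact permutation gave p = 0.343 for the median SD between replicate spots (0.0812 and 0.0722 on the log2 scale) and p = 1 for the median local background (30.0 and 29.75). Adjusted over these 4 measures no p was below 0.686. Arrays correlated at r = 0.960 to 0.991 across features, which are not independent replicates. Along the first principal component, with 42.2% of the variance, hydroxyurea 2 lay at -3.29, the other hydroxyurea arrays at -67.4 to -40.4 and the saline arrays at 36.0 to 55.2. It correlated best with saline 1 (r = 0.989).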

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

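The tests of dim probes, of the other strand and of other splits of the arrays were set before the result was seen, while those of receptor genes, of the histones and of the array hydroxyurea 2 were chosen after.

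Chromosome intervals were called lower in 304 of 2757 cases. By this count dim signal alone did not account for the falls, since the number was 4.42 times the 68.8 expected from named genes of the same signal. Intervals that overlap each other were counted apart and each named gene once, so the ratio compares unlike units. Genomic DNA in the saline RNA would carry both strands. In 177 fallen intervals with a probe on the other strand the median ratio of the other strand's difference to the fallen probe's was -0.0227 (quartiles -0.213 and 0.185). Of the other-strand probes 65.5% were well above background on at least 1 saline array. The ratio speaks only against DNA that gives signal on both strands alike. For unspecific signal in saline the slides differed. Probes of olfactory and related receptor genes, known to be silent in most tissues, were above background in 9.37% of cases in saline and 7.09% in hydroxyurea. For interval probes the shares were 37.9% and 31.3%. The differences were 2.28 and 6.66 percentage points (ratio 0.342), with 4.18 against 8.14 on slide 1 (ratio 0.513) and 0.377 against 5.18 on slide 2 (ratio 0.0728). Because the base shares differ, this ratio does not compare relative changes. The slide 1 values leave unspecific signal open, and the slide 2 values speak against it there. With 2 arrays per group on a slide it cannot be told apart from an effect of the treatment on these transcripts.

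Of 43 replication-dependent histone genes 22 were called lower. A smaller share of cells in late G1 and S phase would lower replication genes as well, but their list had a median of 0.35 with 7 of 44 members below 0. Cross-hybridisation confined to 1 family is unlikely, since 5 families held calls. Cross-hybridisation inside each family would also give calls in 5 families and was not tested. A lower yield of RNA without a poly(A) tail could play a part: 11 small RNAs of that kind had a median of -0.50, a share of 0.433 of the histones' median, and of these Rmrp (-2.004) and Rnu2-10 (-1.51), chosen after their values were seen, were called. It cannot be told apart here from a faster loss of histone mRNA, which is known to follow a stop of DNA synthesis.

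The array hydroxyurea 2 lay nearest the saline arrays. A saline sample under a hydroxyurea label did not account for this, since its mean of the p53 targets was 1.27, against 1.31 on the lowest other hydroxyurea array and 0.0378 on the highest saline array. A response scaled down alike in all groups of genes would give equal shares of the other hydroxyurea arrays' mean shift. The array's shares ran from -0.0235 for hypoxia to 1.53 for mitosis, a range of 1.56 over the 12 called lists and the fallen intervals. The share was 0.405 for replication, 0.879 for p53 targets and 0.976 for histones. It was 0.664 for the fallen intervals, which were picked by their fall, and 0.240 for all 2757 intervals. Of the 13 sets of called lists and fallen intervals, 8 were weaker and 2 stronger than on the other hydroxyurea arrays by more than 1 SD. Each share rests on 1 array, and small shifts make it imprecise, so these differences cannot exclude a response scaled down alike. A weaker response in part of the genes, or a difference in the sample or the array, also stays open and was not tested.

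Of the 35 splits of the arrays into 4 and 4, 1, the true one, gave as many as 1429 called features, and the highest other number was 1. With 35 splits no share below 1 of 35 can be reached, so a chance assignment of arrays was unlikely for this count but not excluded. As many as 12 called lists came from 6 of the splits, with 15 as the highest other number and 6 for the split by slide, so by this count chance was not excluded for the number of lists. The 5 other splits that reached it all put 3 arrays of a group with 1 of the other, which keeps part of the true difference, and the 18 splits with 2 of each on both sides reached at most 9.

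Single arrays stood far from the other 3 of their group by Dixon's criterion in 18 of 248 groups (7.26%), where chance gives about 5%. The values are log2 signals relative to the array's 75th percentile, or list means relative to the saline mean, with the range of the other 3 arrays after each. On saline 1, H2bc18 was at 2.73 (4.12 to 4.23), H2ac4 at 6.87 (7.86 to 7.92) and the mean of the histones at -0.35 (0.11 to 0.12). On saline 2, Amer3 was at -1.12 (-1.90 to -1.79), Ube2c at 5.41 (5.09 to 5.14), Six3 at -0.81 (-0.24 to -0.18) and the mean of the neural progenitor list at -0.22 (0.05 to 0.11). On saline 3, Bik was at -2.34 (-2.90 to -2.82), Edem1 at 0.726 (0.98 to 1.02), the mean of the BCL2 family and caspases at 0.20 (-0.08 to -0.04) and that of the housekeeping genes at 0.18 (-0.07 to -0.05). On saline 4, Sox10 was at 1.09 (0.88 to 0.90). On hydroxyurea 1, Sox10 was at 0.43 (0.03 to 0.10). On hydroxyurea 2, Amt was at -3.17 (-6.53 to -6.14), Bax at 3.94 (4.27 to 4.32) and Hmox1 at 1.77 (2.025 to 2.032). On hydroxyurea 3, Nkx2-2 was at -1.32 (-1.77 to -1.69) and Xist at -1.85 (-0.82 to -0.66).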

How the results depend on the processing

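The 2 alternatives without both the hydroxyurea 2 and saline 2 arrays and with named genes only were chosen after seeing the data. Against 1429 features called (642 higher, 787 lower), fewer were called with no filter on dim probes (615), on slide 1 alone (59) or slide 2 alone (3, with 3464 at an unadjusted p of 0.05), at a fold of at least 2 (834), at an adjusted p of 0.01 (380) and with named genes only (771). More were called with array weights (4107, with the lowest weight of 0.384 on hydroxyurea 2) and without both hydroxyurea 2 and saline 2 (2455). Leaving out each array in turn gave 524 to 3739. The smaller counts on 1 slide follow from fewer arrays, and those at stricter thresholds from the threshold; for the others the cause was not tested. Counts stayed within 1.5 times with the slide (1069) or the position (1211) as a block, all probes tested as they are (2096, 37.1% higher), median centring (1068) and quantile normalization (1843, 51.2% higher), and with probes well above background on all 8 arrays (1553, 52.0% higher), and normexp gave 2100 (54.8% higher).

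Of 27 lists 12 passed. With an estimated correlation 0 passed (4 unadjusted), and by exact permutation 0 passed (8 unadjusted, smallest adjusted p = 0.0964); here 4 arrays per group cap the attainable p. Each array left out in turn gave 11 to 15. The overlap with the authors' table was 952, and 563 when a fold of at least 2 was asked, which follows from the threshold. Bard1 reversed to -0.0961 with the mean of its probes (adjusted p = 0.75), which follows from its other probes of opposite sign.

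Among 1080 comparisons of the 72 called named genes with their alternatives 766 kept sign and side of the threshold, 313 kept the sign and no longer passed, and 1 reversed. Of the 72, 19 passed on slide 1, 0 on slide 2 and 57 with the slide as a block. Without each array in turn 45 kept their call, 27 lost it at least 1 time, and 10 genes not called passed without hydroxyurea 2. Among 228 comparisons of called lists 194 kept their call and 34 did not, with no reversal. No paired analysis was possible because the labels do not tie hydroxyurea and saline samples of an experiment to each other; the position on the slide, which joins 1 array of each group but no experiment, served as a block instead (1211, 452 higher). Signal over background limits the size of changes in dim genes: normexp compressed these.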

Other observations

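The groups of genes in the next paragraph were chosen after the result was seen, while the test of gene length was set before.

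Groups of genes put together only after the data were seen gave further falls among regulators of development. Of 199 measured members of developmental transcription factor families 22 fell and 1 rose, with a median of -0.23 (camera p = 6.0e-07 unadjusted, 0.065 with an estimated correlation, beside 22 falls by Fisher's exact test at p = 1.1e-10, with genes treated as independent). Sox14 (-3.06), Sox8 (-2.93), Foxf1 (-1.65), Foxo4 (-1.52) and Lhx1 (-1.10) fell and Foxj1 (1.09) rose, each chosen after its values were seen. In 19 measured genes of MHC class I antigen processing 3 rose and 0 fell (camera p = 0.13 beside Fisher's exact p = 0.03), with Tap2 (1.33) and Psmb9 (1.58), also chosen after their values were seen, beside Tap1. In 47 measured signalling antagonists 3 fell and 0 rose (camera p = 0.44 beside Fisher's exact p = 0.07), namely Lfng, Spry2 and the hedgehog receptor gene Ptch1 (-2.15, chosen after its values were seen). These p-values come from groups picked by their values and are no test of them.

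A hypothesis was that longer genes fall more, as a block of transcript elongation might produce. Spearman's rho of the log2 difference and genomic length was 0.123 across 14631 named genes (0.12 among 14344 protein-coding genes, 0.0691 to 0.144 on single hydroxyurea arrays), against this hypothesis. In the fifth with the shortest genes (median 3.64 kb) the median log2 difference was -0.0081 and 3.31% were lower, and in the fifth with the longest (median 118 kb) it was 0.15 and 1.71% were lower. Genes are not independent replicates, so no p is given.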
